A study of Thermococcus onnurineus NA1 with 8 samples.

How the data were processed

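Expression was measured in Thermococcus onnurineus NA1, a hyperthermophilic archaeon, on a custom Roche NimbleGen array. Per the labels' protocols, cells were grown without oxygen at 80 °C in a medium that held sodium formate at 10 g/L, yeast extract at 1 g/L and NaCl at 35 g/L. Total RNA was extracted with TRIzol and treated with DNase, and 5 µg per sample was labelled with Cy5 during reverse transcription. Each sample was hybridised alone, in 1 colour. The series' design text describes 6 probes of 60 nucleotides for each of 1986 predicted open reading frames (ORFs).

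The deposited values are RMA intensity values on a linear scale, per the file headers, which name an expression value and its standard error for each set of probes. RMA is also named by the submitters' processing notes, without a version. Background correction, the normalization settings and the software version are not given in the sources used here. The distributions of the 8 arrays nearly coincided: over all features, quantiles from the 5th to the 95th percentile differed between arrays by a median of 0.087 on the log2 scale and by at most 0.252. The values were therefore used as deposited, without a further normalization in the main analysis. The value table of the whole series held the same intensity values, with 0 cells differing. No scanner flags for dim or saturated spots were used here, and the standard errors were not used because their scale is not given.

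The array carries several families of features. The 1970 features whose names begin with NA1_ORF had a median of 13.0 on the log2 scale, and each was printed in 2 blocks of up to 3 probes. The 2 block values of a feature differed with an SD between 0.161 and 0.271 within an array, and their mean on the log2 scale was used. The families named NA2, OT, SC and CONTIG had medians between 6.59 and 7.05, close to the random control probes, and were used only to set a background limit. That limit was the 95th percentile of those families on each array, between 7.76 and 7.97, and a feature under it on both arrays of a group has only a bound there. For such a feature the fold is given as "at least", against the higher of the limit and the measured value on each array. Between 98.3% and 99.7% of the NA1_ORF features were above the limit on each array. The number of arrays limits the precision of all comparisons.

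The feature names are not paired with gene names or locus tags in the files. None of the 1970 names (0) matched the annotation table of assembly ASM1836v1, which lists 1993 locus tags of the form TON_0001, and the feature numbers run to 2791 with gaps, so they are not locus tag numbers. Genes are therefore not named. The targeted genes could not be looked up by name. The 27 gene lists planned by locus tag or product (hydrogenase, formate, redox, translation and other lists), with camera and fry as their tests, could not be filled and were not run. In their place, and chosen after the data were seen, runs of features were described: at least 3 features in a row, in the order of their numbers, that differed by at least 1 on the log2 scale in the same direction. The excess of runs over a random feature order was tested by shuffling the order of the features 1000 times. This asks whether neighbouring features differ together, not whether a mutant differs from wild type. That the numbers follow the chromosome is not stated in the sources used here. At most 2 features that rose and 2 that fell are named per comparison. These are the largest changes past the threshold whose groups do not overlap, a shortened form of a planned rule for 10 each way that relied on gene products. For the TON_0282 comparison they are the largest differences with the mutant outside the range of all 3 wild-type arrays. NA1_ORF02200 and the runs were singled out after their values were seen.

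The 8 arrays fell into 5 groups by their titles: frhA deletion (2), overexpression of the frh gene cluster (2), WT 1 and WT 2 (2), the TON_0282 deletion (1) and a further wild-type array (1) that the labels name as the control of the TON_0282 deletion. The labels describe replicates of the groups of 2 as separate cultures. Titles, sources and genotypes set the groups. The free-text descriptions differ from them in a phrase: those of the frhA deletion arrays speak of wild-type replicates, and those of WT 1 and WT 2 of mutant replicates. The direction of the frhA deletion and frh overexpression comparisons rests on the titles and genotypes. The names of the deposited files place the 4 frh mutant arrays on 1 slide and the other 4 arrays on another, so the slide and the group cannot be told apart when the frh mutants are compared with the wild type. A fit with the slide as a block could not be made for those comparisons. The comparison of the mutants with each other and the TON_0282 comparison lie within a slide.

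Differences were tested with limma (lmFit and eBayes) version 3.58.1 in R 4.3.3, in 1 fit of all 8 arrays and 5 groups. The spread came from the 3 groups of 2 arrays (3 residual degrees of freedom, 4.83 prior degrees of freedom). Features with a Benjamini-Hochberg adjusted p under 0.05 over 1970 features are called; SE values are limma's moderated errors. The TON_0282 deletion and its wild type had 1 array each, so the change of a feature was not tested in the main comparison and differences of at least 1 on the log2 scale were counted. A limma fit with all 3 wild-type arrays as 1 group was an alternative, and the shuffling of the feature order describes these arrays, not the conditions. Alternatives fixed before the data were examined were the value table, quantile normalization, median centring, the median of the block values, leaving out the dimmest 20% of features, an intensity trend, only the arrays compared, the replicate number as a block, leaving out each array of a group of 2 (the array left alone in its group is then assumed to vary like the other groups), a threshold on the change, and all 3 wild-type arrays as 1 group. Each printed block alone, the run definitions, a crossed pairing, a separate control array for each mutant in the overlap and the comparison of the single wild-type array with WT 1 and WT 2 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

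The test was checked on simulated arrays, in which 66 or 67 features were changed by each size. All simulated arrays took the means of the second group compared, with independent normal noise of limma's moderated variances. For the frhA deletion against wild type, 60.6% of simulated changes of 1 on the log2 scale, 97.0% of changes of 2 and 100% of changes of 3 were called, and 3.91% of the calls were unchanged features. For frh overexpression against wild type the shares were 57.6%, 100% and 100%, with 3.37% false calls. For the mutants against each other they were 47.0%, 100% and 100%, with 7.30% false calls. These shares hold for that noise and that number of changed features, so they do not show that uncalled changes are absent. In the real arrays, a run of 15 features was higher in the frhA deletion than in wild type by a mean of 2.23, with 1 called.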

Results

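Transcript levels were compared between wild-type Thermococcus onnurineus NA1 and 3 mutants grown on formate: a deletion of frhA, a strain overexpressing the frh gene cluster, and a deletion of the gene TON_0282. Frh is the usual name of the F420-reducing type of hydrogenase, and frhA names its large subunit. The series holds 8 arrays: 2 of the frhA deletion, 2 of the frh overexpression strain, WT 1 and WT 2 as their controls, and 1 array each of the TON_0282 deletion and its wild-type control. Levels are RMA values on the log2 scale over 1970 features. The median feature lay between 12.94 and 13.05 on every array. No gene names were paired with the features, so features carry the array's names, and groups are given as runs of features with neighbouring numbers.

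The wild-type array of the TON_0282 comparison correlated less well with WT 1 and WT 2 than the frh mutant arrays did, and some arrays of different genotypes were as close as replicates. WT 1 and WT 2 correlated at r = 0.98 across features, the frhA deletion arrays at 0.94 and the frh overexpression arrays at 0.94. The wild-type array of the TON_0282 comparison correlated at only 0.68 with WT 1 and 0.71 with WT 2, although these arrays shared a slide. Its correlation with the TON_0282 deletion array was 0.85. These are correlations across features within pairs of arrays, and features are not independent replicates. By count, 50 features differed by at least 1 on the log2 scale between WT 1 and WT 2, 115 between the frhA deletion arrays and 178 between the frh overexpression arrays. Across genotypes, frhA deletion replicate 2 and frh overexpression replicate 1 correlated at 0.94 with 143 features that far apart, and frhA deletion replicate 1 and WT 1 had 120. The wild-type array of the TON_0282 comparison differed by that much from WT 1 at 705 features. The TON_0282 deletion array differed by that much from its wild type at 491 features, from WT 1 at 264, from WT 2 at 263 and from frhA deletion replicate 1 at 171.

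**Figure D1:**
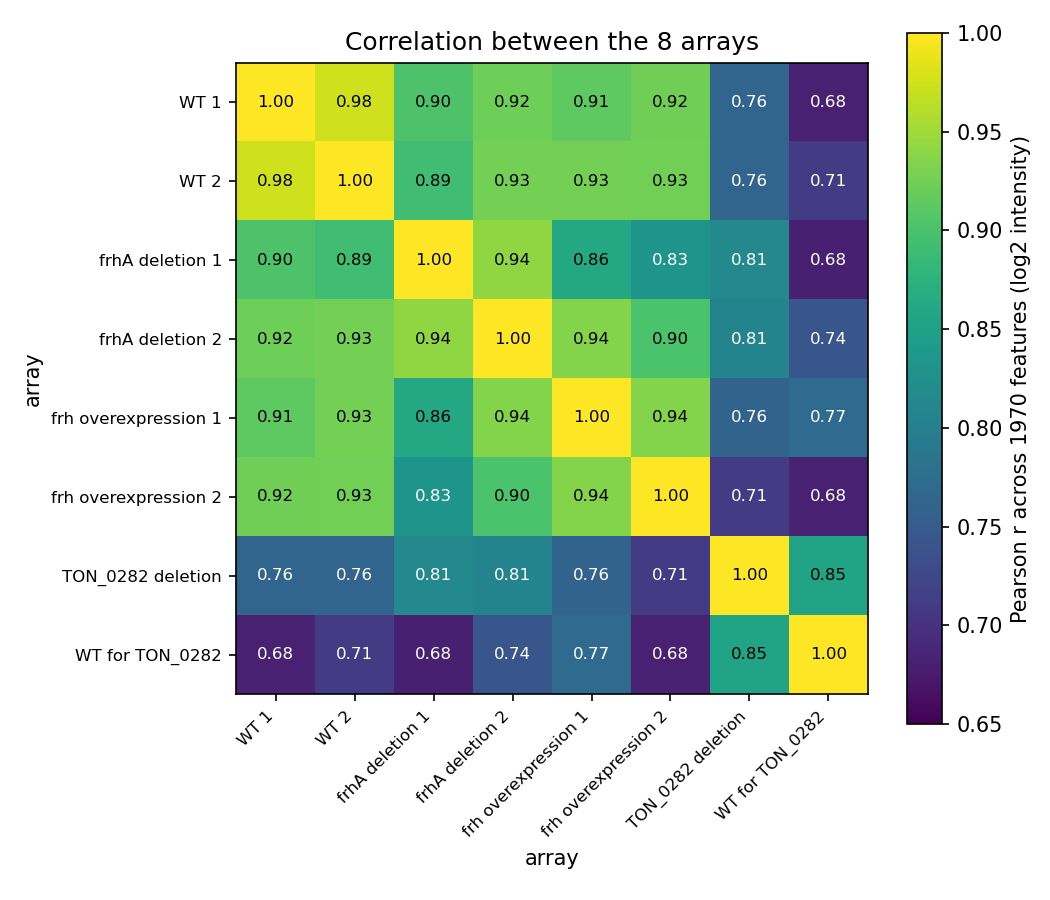
Pearson correlation of log2 RMA intensity across 1970 features for each pair of the 8 arrays, with r printed in each cell. WT 1 and WT 2 correlate at 0.98, and the wild-type array of the TON_0282 comparison correlates with them at 0.68 and 0.71.

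The targeted genes were examined through the pattern a deletion would leave, since they could not be looked up by name. No feature was at least 1 lower on the log2 scale in both frhA deletion arrays than in the other 6 arrays (0 features, widest gap 0.742). In replicate 1 alone, NA1_ORF02200 was near background, at 7.70, while replicate 2 had 15.73 and the other 6 arrays lay between 14.99 and 15.73. Its difference from wild type was -3.53 on the log2 scale with an SE of 2.04, which did not pass limma's test (adjusted p = 0.743). For overexpression, no feature was at least 1 higher in both frh overexpression arrays than in the other 6 (0 features, widest gap 0.798). The descriptions of the frhA deletion arrays also speak of wild-type replicates, in conflict with their titles and genotypes. In the reverse check, chosen after the data were seen, 1 feature, NA1_ORF02493, was at least 1 lower in WT 1 and WT 2 than in the other 6 arrays (gap 1.48). It stayed above background there, at 10.18 and 10.37, and 4 features were below the background limit only in WT 1 and WT 2. The matching count for the frhA deletion arrays was 0. WT 1 and WT 2 were not above background at 7 features of a run of 12 described below. The count of 4 therefore does not single out a removed gene. Features close to the top of the scale, which reached 15.92, have little room to rise. No feature (0) was below the background limit in the TON_0282 deletion array and above it in its wild type.

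The comparison of the frhA deletion with wild type asks which transcripts respond to the loss of frhA. A single run of 12 features with neighbouring numbers was higher in the deletion, by a mean of 4.85 on the log2 scale as measured (SD over features 1.56) and of at least 4.50 with features below background at their bound, and all 12 were higher in both deletion arrays than in WT 1 and WT 2. Of these 12 features, 11 passed the test. Within the run, NA1_ORF00745 rose from 6.77 ± 0.07 (SD, n = 2) to 12.90 ± 0.19 (SD, n = 2). The increase was 6.14 ± 0.31 (SE; limma adjusted p = 5.15e-05), and since the wild-type level was not above background this is an at least 30.5-fold rise. NA1_ORF00740 rose from 7.47 ± 0.01 (SD, n = 2) to 13.58 ± 0.92 (SD, n = 2), an at least 48.9-fold rise (limma adjusted p = 0.000523). At 7 of the 12 features the wild type was not above background, and with those at their bound the median difference of the run was 5.04 instead of 5.73.

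A run of 15 features was higher by a mean of 2.23 on the log2 scale (SD over features 0.38), with 1 of them past the test. Its mean level was 14.56 in replicate 1 and 12.96 in replicate 2 of the deletion, against 11.50 in WT 1 and 11.57 in WT 2. The wild-type array of the TON_0282 comparison had 8.98, so wild-type arrays also differed widely in this run. A run of 8 features that did not pass the test was higher by a mean of 1.72, and in a run of 7 features, higher by 1.34, 1 passed. In all, 7 runs with 52 features were higher, against a mean of 0.46 features in runs when the order of the features was shuffled (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). Shuffling treats neighbouring features as independent, so this p-value concerns the feature order and not an effect of the deletion. The wild-type array of the TON_0282 comparison, set against WT 1 and WT 2, had 295 features in runs, against 54.2 in shuffled order.

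Across all features, 15 rose and 0 fell in the frhA deletion at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 126 higher and 43 lower features, and limma with an intensity trend called 46 higher and 0 lower. The groups did not overlap at 44.5% of features, where chance gives 33.3%. Without frhA deletion replicate 2, 38 features were called (35 higher and 3 lower), and without WT 1, 9. With all 3 wild-type arrays as 1 group limma called 0, with 96 features at an unadjusted p under 0.05. The run of 12 features had a mean level of 14.41 on that additional wild-type array, against 13.66 and 12.99 in the deletion and 8.54 and 8.41 in WT 1 and WT 2. The mutant and wild-type arrays lay on different slides, so slide and group cannot be told apart from this comparison alone. Against the overexpression arrays of the same slide, 14 of the 15 features were also called and the run of 12 was higher by a mean of 4.41.

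**Figure D2:**
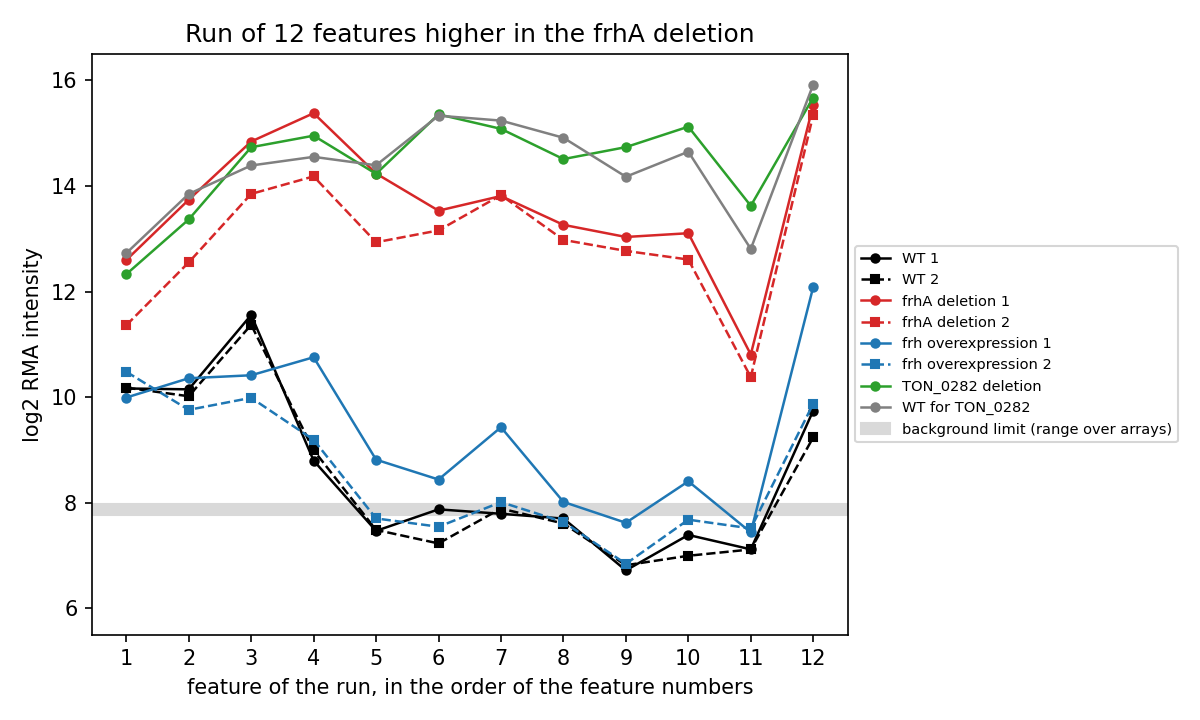
Log2 RMA intensity on each of the 8 arrays for the run of 12 features that was higher in the frhA deletion, in the order of the feature numbers, with the grey band marking the range of the background limits. The run is high in both frhA deletion arrays (means 13.66 and 12.99) and in the TON_0282 deletion and its wild type (14.48 and 14.41), and low in WT 1, WT 2 and the frh overexpression arrays (means 8.41 to 9.31).

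The comparison of the frh overexpression strain with wild type asks which transcripts respond to more of the frh cluster. In a run of 5 features, higher by a mean of 2.43 on the log2 scale (SD over features 0.59), 3 rose past the test. The run's mean level was 13.70 and 13.12 in the overexpression arrays, 10.92 and 11.05 in WT 1 and WT 2, and 13.70 on the additional wild-type array. NA1_ORF01185 rose from 10.76 ± 0.27 to 13.69 ± 0.24 (SD, n = 2 each), a 7.67-fold rise (limma adjusted p = 0.0331). Its neighbour NA1_ORF01184 rose 7.58-fold (log2 difference 2.92, SE 0.38, limma adjusted p = 0.0331). NA1_ORF00181 fell from 12.98 ± 0.01 to 10.37 ± 0.43 (SD, n = 2 each), a 6.12-fold drop (limma adjusted p = 0.0367). On the additional wild-type array NA1_ORF00181 had 10.86, nearer to the overexpression arrays than to WT 1 and WT 2. NA1_ORF01494 fell from 14.40 ± 0.28 to 12.39 ± 0.35 (SD, n = 2 each), a 4.01-fold drop (limma adjusted p = 0.0479), and it was not called after median centring. The run of 3 that holds NA1_ORF01494 had a mean level of 12.78 on the additional wild-type array. The overexpression arrays had 12.66 and 12.20 there, and WT 1 and WT 2 had 14.06 and 13.86. A run of 6 features that did not pass the test was lower (mean difference -1.89 on the log2 scale). On the additional wild-type array it had 9.44, below both overexpression arrays (10.03 and 11.18).

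In total 6 features rose and 2 fell in the frh overexpression strain, and after median centring of the arrays 6 rose and 1 fell. With limma, all 8 calls were lost when any 1 of the 4 arrays was left out (0 called in each case, with 157 to 381 features at an unadjusted p under 0.05) and with all 3 wild-type arrays as 1 group (0 called, 143 at an unadjusted p under 0.05). With an array left out, the change lay between 2.75 and 3.13 on the log2 scale for NA1_ORF01185 and between -2.31 and -2.92 for NA1_ORF00181. Its direction could not reverse, since named features were chosen for groups that do not overlap. The SE for NA1_ORF01185 was 0.37 with all arrays and 0.47 to 0.49 with an array left out. A larger error from fewer arrays can lose calls, so their loss does not show that they depend on 1 array. With an intensity trend limma called 32. Runs held 26 higher and 9 lower features (13 in all with differences of at least 1.5), against a mean of 0.44 features in shuffled order (one-sided permutation p = 0.001, the smallest possible). Here too the p-value concerns the feature order and not an effect of overexpression. The groups did not overlap at 47.8% of features, where chance gives 33.3%. The overexpression and wild-type arrays lay on different slides, so slide and group cannot be told apart from this comparison alone. Of the 8 features, 4 were also called between the overexpression and deletion arrays of the same slide, though both comparisons use the same overexpression arrays. NA1_ORF00181 was among them, 2.34 higher on the log2 scale in the deletion (limma adjusted p = 0.0228), where it differed from wild type by -0.28.

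The mutants were also compared with each other, within a slide. The run of 12 features was higher in the frhA deletion than in the overexpression strain by a mean of 4.41 on the log2 scale (SD over features 1.19), and 11 of the 12 passed the test. NA1_ORF00745 was higher by 5.67 ± 0.31 (SE; limma adjusted p = 9.42e-05), which is at least 32.4-fold because the overexpression arrays were not above background. NA1_ORF00742 was 40.9-fold higher (limma adjusted p = 0.000309), with 1 of the 2 overexpression arrays above background. Among a run of 15 features, higher by a mean of 2.42, 8 passed the test. Of a run of 9 features, higher by 2.18, 7 passed, and of a run of 7, higher by 1.60, 6 passed. In the other direction, NA1_ORF00911 was 3.90-fold lower in the deletion (10.56 ± 0.22 against 12.53 ± 0.46, SD, n = 2 each; limma adjusted p = 0.0173), and NA1_ORF01186 was 2.94-fold lower (limma adjusted p = 0.03).

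Between the mutants 41 features were higher in the frhA deletion and 4 were lower. Of the 15 features called in the deletion against wild type, 14 were also called here, where independent lists would share 0.34, though both comparisons use the same deletion arrays. The count depended on the arrays: 18 without frhA deletion replicate 1 (18 higher), 81 without replicate 2 (55 higher and 26 lower), 24 without frh overexpression replicate 1 (24 higher) and 12 without its replicate 2 (11 higher and 1 lower). NA1_ORF01186 was called only in the fit without frhA deletion replicate 2 among these 4. With only the 4 arrays compared, limma called 23 higher and 0 lower, with 195 features at an unadjusted p under 0.05, so the named lower features were not called there.

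The fold changes of the mutants against wild type correlated at r = 0.34 across features (Spearman's rho 0.47). Because both use WT 1 and WT 2, unchanged groups would give a mean r of 0.50 in 200 simulations. The covariance was 0.120 against 0.0507 in the simulations, a difference of 0.0697. With all 3 wild-type arrays as 1 group it was 0.127 against 0.101, a smaller difference of 0.0254, and r was 0.35 against a simulated 0.40. The same sign was shared by 66.7% of features, against 66.6% in the simulations. Of the 15 and 6 features that rose, 1 was shared, where independent lists would share 0.046, a value that leaves out the shared controls. With a separate control array for each mutant, an alternative chosen after the data were seen, the covariance was 0.10 with WT 1 for the deletion and WT 2 for overexpression (r = 0.27), and 0.064 the other way round (r = 0.16). These have no shared control array, but each rests on 1 control array per mutant. Both mutants lay on 1 slide and all control arrays on the other, and the simulations held no slide difference. A slide difference would enter both fold changes alike, so the covariance cannot be told apart from it.

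The TON_0282 deletion was compared with the wild-type array that the labels name as its control, with 1 array on each side and no replicate check. A run of 14 features was higher in the deletion by a mean of 2.42 on the log2 scale (SD over features 0.65). Its mean level was 14.83 in the deletion and 12.41 in its wild type, and between 8.19 and 9.23 on the other 6 arrays. NA1_ORF00387, a member of that run, had 13.88 against 10.06, a 14.1-fold difference. NA1_ORF01671, in a run of 9 features that was higher by a mean of 2.22, had 13.56 against 10.26, a 9.85-fold difference. Against WT 1 and WT 2, NA1_ORF00387 differed by 5.64 on the log2 scale. NA1_ORF01671 had 12.52 in WT 1 and 11.61 in WT 2, closer to the deletion than its named control was. A run of 17 features was higher than in the named control by a mean of 2.41 but not higher than in both other wild-type arrays (11.97 in the deletion, 9.56 in its wild type, 12.54 in WT 1 and 11.95 in WT 2). A run of 8 was higher by 2.14 against the named control alone (13.62 against 11.48, with 13.64 in WT 1 and 13.91 in WT 2). Lower in the deletion were NA1_ORF02734, with 8.04 against 13.09, a 33.0-fold difference, and NA1_ORF01364, with 9.86 against 14.57, a 26.2-fold difference. Against WT 1 and WT 2, NA1_ORF01364 differed by only -0.52 on the log2 scale and NA1_ORF02734 by -3.96. A run of 7 features was lower than in the named control (mean difference -1.53) but higher than in WT 1 and WT 2 (12.99 against 11.11 and 11.21). A run of 6 was also lower than in the named control (mean difference -1.82). Its mean of 11.41 lay near WT 2 (11.17) and above WT 1 (10.80).

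**Figure D3:**
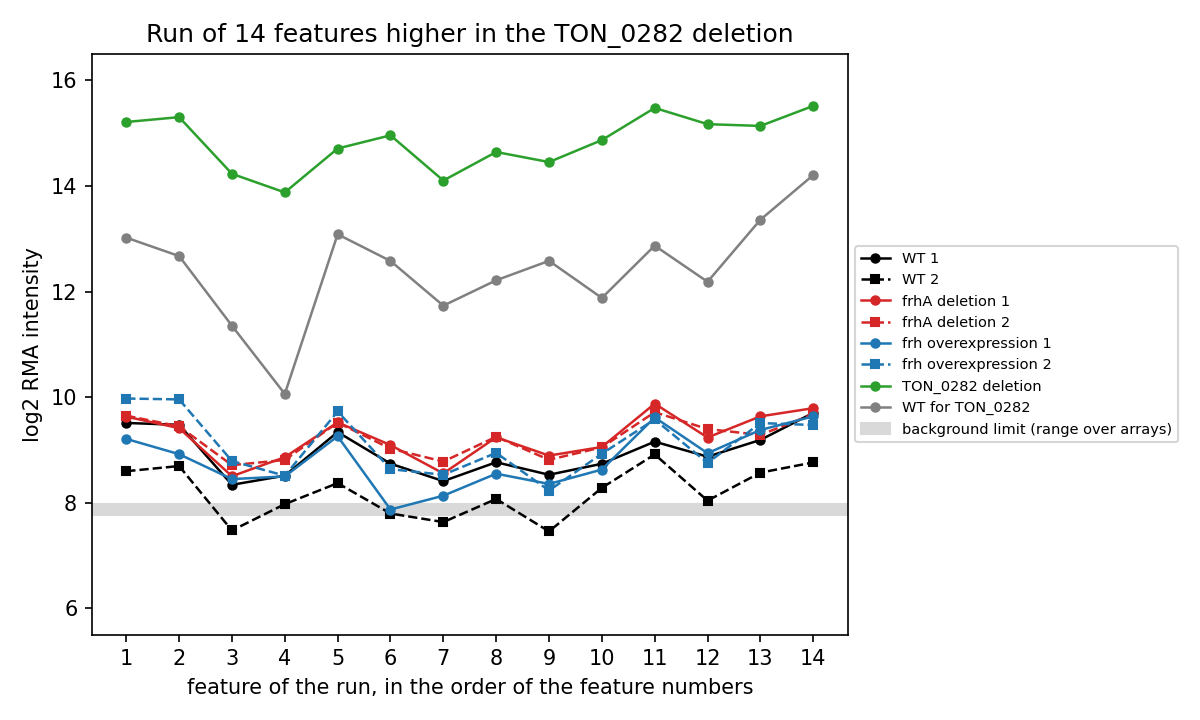
Log2 RMA intensity on each of the 8 arrays for the run of 14 features that was higher in the TON_0282 deletion than in its wild type, in the order of the feature numbers, with the grey band marking the range of the background limits. The run's mean is 14.83 in the TON_0282 deletion, 12.41 in its wild type and at most 9.23 on the other arrays.

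In this comparison 325 features were at least 1 higher on the log2 scale in the deletion and 166 were at least 1 lower. Of these 491, 179 lay outside the range of all 3 wild-type arrays, 118 above it and 61 below it. No chance share was worked out for this count. A lone array can lie outside such a range at many features without an effect of the deletion. Features in runs numbered 175, against a mean of 26.8 in shuffled order (one-sided permutation p = 0.001, the smallest possible), and 62 when a run needed differences of at least 1.5. Again the p-value concerns the feature order and not an effect of the deletion. Against WT 1 and WT 2 in place of the named control, 237 features differed by that much, and 68 of them were among the 491 in the same direction. In a limma fit with all 3 wild-type arrays as 1 group, which assumes that the lone mutant array varies like the other groups, 0 features were called and 100 had an unadjusted p under 0.05 (smallest adjusted p = 0.565).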

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

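The counts in this part were chosen after the data were seen. The families of features not used in the comparisons held a few signals on all 8 arrays, counted as at least 2 above the random control probes on the log2 scale. There were 10 such features of 1969 in the NA2 family, 9 of 4073 in the OT family, 7 of 2351 in the SC family and 0 of 327 in the CONTIG family, against 1807 of 1970 in the NA1_ORF family. The brightest NA2 feature averaged 14.94 on the log2 scale.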

How the results depend on the processing

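Quantile normalization and median centring kept the total number of calls in each of the 3 tested comparisons within 1.5 times. Median centring gave 1 lower call instead of 2 for frh overexpression. Each printed block alone, chosen after seeing the data, also stayed within 1.5 times. The value table held the same values and the median of 2 block values is their mean, so neither could change a call. A threshold of 1 on the log2 change could not either. The smallest called changes were 1.46 for the frhA deletion, 2.00 for frh overexpression and 1.39 between the mutants. Of the values for named features and runs, 95 under the settings listed in advance kept their direction and side of the threshold, 35 kept their direction but no longer passed it and 9 untested values moved. Under the settings added after seeing the data these numbers were 26, 5 and 5, and none changed direction. The 95 include values under the value table and the median of the block values, which were bound to be the same. Leaving out an array could not reverse the direction of the named tested features, since their groups do not overlap. Leaving out the dimmest 20% of features gave 8 calls instead of 15 for the frhA deletion, 27 instead of 45 between the mutants and 305 differences instead of 491 for the TON_0282 deletion, with fewer features available to call. An intensity trend gave 46 calls for the frhA deletion and 32 for frh overexpression. Only the arrays of the 2 groups gave 23 calls between the mutants. All 3 wild-type arrays as 1 group gave 0 calls for the frhA deletion and 0 for frh overexpression, and the added wild-type array differs widely from the other wild-type arrays. Leaving out 1 array gave 9 to 38 calls for the frhA deletion, 0 to 0 for frh overexpression and 12 to 81 between the mutants. For the TON_0282 deletion, the mean of all 3 wild-type arrays gave 178 differences of at least 1 and WT 1 with WT 2 gave 237. The deviations of same-numbered replicates correlated at 0.17 (frhA deletion and wild type), -0.17 (frh overexpression and wild type) and -0.04 (the mutants), and with only 2 numbers they were not taken to pair the samples. With a replicate block there were 19 calls for the frhA deletion, 0 for frh overexpression and 39 between the mutants. A replicate block with crossed numbers, added after the data were seen, gave 2 calls for frh overexpression. The correlation of the mutants' fold changes was 0.35 with all 3 wild-type arrays, against 0.40 in simulations, and 0.27 and 0.16 with a separate control array for each mutant, which was chosen after seeing the data. With runs of differences of at least 1.5, chosen after seeing the data, features in runs fell from 35 to 13 for frh overexpression, from 77 to 43 between the mutants and from 175 to 62 for the TON_0282 deletion. Apart from these, the cause of each shift was not tested. The block with the slide could not be fitted and the gene lists were not run. Signal near the background limit bounds the folds of dim features, and levels near the top of the scale limit the size of a rise.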

Other observations

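All tests in this part were chosen after the results were seen. The wild-type array of the TON_0282 comparison differed from WT 1 and WT 2 in long blocks of features, although the labels give the same genotype and medium. These are differences of 1 array, with no replicate check. A run of 18 features beginning at NA1_ORF00378 was higher by a mean of 3.53 on the log2 scale, and a run of 14 beginning at NA1_ORF00732 by 5.40 as measured. The run of 14 holds the run of 12 described above, where 7 features were not above background in WT 1 and WT 2. Its mean therefore rests in part on levels that have only a bound. In the other direction, a run of 17 features beginning at NA1_ORF02209 lay at a mean of 11.05 against 15.33 and 15.22 (mean difference -4.23), and the TON_0282 deletion array had 10.84 there. A run of 17 beginning at NA1_ORF02617 had a mean difference of -2.69. In all, this array was at least 1 higher on the log2 scale than the mean of WT 1 and WT 2 at 270 features and at least 1 lower at 394.

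For the distance of the single wild-type array from WT 1 and WT 2, a slide difference is argued against: its highest correlation with WT 1 and WT 2, on its own slide, was 0.711, below the lowest of 0.893 that the frh mutant arrays of the other slide reached. Noise of that array as the whole cause was examined on the TON_0282 deletion array. Of the 705 features at least 1 apart from WT 1, 74.8% lay on the same side of WT 2 there, against a mean of 50.9% when the feature order was shifted. With WT 1 and WT 2 exchanged 84.1% did, and both shares exceeded those of all 1969 shifts. The shifts do not keep the level of each feature, and agreement that follows from the level alone was not removed. The test therefore does not settle whether noise is the whole cause. Mean levels in the run of 14 were 14.27 and 14.13 on the single wild-type and TON_0282 deletion arrays. WT 1 and WT 2 had 8.91 and 8.82. In the run beginning at NA1_ORF02209 the levels were 11.05 and 10.84, against 15.33 and 15.22. Noise of 1 array does not recur on another, so these values argue against noise in those 2 runs. In the run beginning at NA1_ORF02617 the TON_0282 deletion array had 11.97, near WT 1 (12.54) and WT 2 (11.95). Noise stays open there. Whether a culture or preparation was shared with the TON_0282 deletion array stays open, since these arrays correlated at 0.854 against at most 0.764 with WT 1 and WT 2, but 491 features lay at least 1 apart, against 264 and 263. The labels name no such difference, and no biological explanation was tested.

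The run of 12 features was higher in both frhA deletion arrays than in WT 1 and WT 2. The slide is argued against, since the difference to the frh overexpression arrays of the same slide was 4.41 (SD over features 1.19). A culture difference that does not need the frhA deletion stays open as a hypothesis: the additional wild-type array reached a mean of 14.41 in this run against 13.33 in the deletion, and 10 of the 12 features were higher there than in both deletion arrays. The frhA genotype also stays open, as the design cannot separate it from a difference between cultures.

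NA1_ORF02200 was near background only in frhA deletion replicate 1, while its neighbours in number differed between the replicates by -0.88 to 0.03 on the log2 scale. This is the pattern that a removed gene might leave, and whether the feature is frhA was not tested because names are not paired with features. A local defect of the array is argued against, since both printed blocks were low, the smaller gap to the lowest other array being 7.15 on the log2 scale. Whether replicate 2 belongs to the frh overexpression or the WT 1 and WT 2 group was also examined. Features were chosen on replicate 1 against 3 of the 4 arrays of these groups. Replicate 2 was at least 1 above the 3 at 63.8% or more of them. The array left out was that high at 6.78% or fewer, and the single wild-type array at 25.9% to 28.8%. At these features replicate 2 thus resembled replicate 1 more than those arrays did. A wild-type array also passed at some of them, and neighbouring features can rise together. The shares therefore do not settle which cells replicate 2 came from. The rank correlation of replicate 2 with frh overexpression replicate 1 (0.943) was as high as with frhA deletion replicate 1 (0.941). Whether replicate 2 comes from cells that kept the feature cannot be told apart from a mixture of cells: its level of 15.73 lay at the top of the range of the other groups (14.99 to 15.73), near the top of the scale.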
